A study of Mus musculus with 24 samples.

How the data were processed

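Microglia from the cortex of mice aged 5.5 months were profiled by bulk RNA sequencing in 24 samples. Per the labels' protocols, cortex was dissociated, myelin was removed on a Percoll gradient, and cells with CD11b and low to intermediate CD45 staining were collected by flow cytometry. RNA went through SMART-seq v4 pre-amplification, which copies polyA RNA with template switching followed by PCR, and Nextera XT tagmentation, neither of which marks strand. Both kits use PCR, and no molecular identifiers are named, so the floor of 3 counts given below covers counting error only. Standard deviations and standard errors come from the spread between libraries.

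The deposited count table holds whole-number read counts per gene symbol, with 56832 genes and 24 libraries. STAR 2.7.9a, Subread 2.0.1, featureCounts and the mouse build GRCm39 are named in the submitters' processing notes. The annotation release, the strand setting, the treatment of reads shared between genes and the read filters are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies (H2-Q6 and the other class I genes, Ifit3 and Ifit3b, Lilrb4a and Lilrb4b, Ccl3 and its relatives, ribosomal proteins with pseudogenes) may therefore have been split or lost, and their values are less certain. A second deposited table holds a normalised signal per gene, which the authors made by dividing each library's counts by 1 size factor. That was checked on the values: the recomputed median-of-ratios size factors differed from the deposited ones by at most 4.44e-16. The normalised table entered no test. The reference annotation at hand was GENCODE M21, built on GRCm38, so no coordinates are printed. It served only for chromosome membership, transcript length and GC content, and it held 91.1% of the symbols with a count.

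Groups were taken from the sample titles: proestrus, diestrus and male, each in BL6 and 5xFAD, with 4 libraries per group. The labels do not say that replicates of a group were separate animals, so p-values measure only the spread between these samples. Totals ran from 47 M to 71.1 M counts per library, with a median of 54.5 M. At that depth 3 counts, the number a count of 0 allows, corresponded to 0.0616 CPM in proestrus BL6 replicate 1. Counts of replicates were compared pairwise by a chi-square statistic. Its smallest value per degree of freedom was 19.5, so no pair of libraries agreed within sampling noise and all 24 were kept.

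The comparisons, tests, gene lists, rule for naming genes and alternative settings were fixed before the data were examined. Genes were filtered with filterByExpr (minimum count 10), which left 18546 of the 33474 genes with at least 1 count. edgeR 4.0.16 (R 4.3.3) fitted 1 quasi-likelihood model with a mean per group, TMM scaling and robust dispersion to all 24 libraries, which thus shared 1 estimate of the spread per gene. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. "edgeR adjusted p" means this value throughout. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. There were 13 comparisons: 5xFAD against BL6 within each sex and cycle group and averaged over the 3, proestrus against diestrus and each female group against males within each genotype, and the 3 differences between genotype effects. CPM values are scaled by TMM. No fold is given for genes near 0 CPM in either group.

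The 33 gene lists covered microglial states, immune and metabolic pathways, hormone and clock genes, sex chromosome genes and markers of the other cell types that a brain myeloid gate could hold. Each list with at least 3 tested members was compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01. Its p-values were adjusted over the lists of a comparison ("camera adjusted p"). The same test with an estimated correlation was an alternative, and its p, or the smallest over several lists, is given where it ends a call. Counts of list members are given over all genes tested and, separately, adjusted over the list alone. In the comparisons of a single group with another, genes at 0 in every library of a group were set to the bound that 3 counts per library allow. With these bounds 6 list medians moved, by at most 0.24. The averaged genotype contrast and the differences between genotype effects were not checked in this way. A list level is the mean log2 CPM of the tested members in 1 library (prior count 2), compared by two-sided exact permutation tests. For 4 against 4 libraries the smallest two-sided p is 0.0286.

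Named genes were a panel of 12 microglial genes (Trem2, Apoe, Cst7, Itgax, Clec7a, Spp1, Lpl, Gpnmb, P2ry12, Tmem119, Cx3cr1 and Sall1). For each genotype comparison they also included the 6 highest and 6 lowest log2 fold changes among called genes with a mean log2 CPM of 2 or more and no overlap between groups. The 4 members with the smallest p of each list described were eligible too. In the cycle, sex and interaction comparisons every called gene was named where 10 or fewer passed, otherwise the 5 highest and 5 lowest outside the sex chromosomes, and the 3 smallest p where none passed. The rule also took levels of steroid receptors and of transgene-related genes, among them App and Thy1. Some genes it takes are not reported here. Predicted or unnamed genes and pseudogenes were only counted, and none was replaced by the next gene. Genes named outside this rule are marked where they appear.

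The model was tested on simulated data with the real library sizes and the mean BL6 level of each gene in every group, and 17863 genes passed its filter. The changed genes were drawn from those with a mean of 4 CPM or more, so the shares recovered hold for such genes only. For the genotype comparison in proestrus it recovered 58.2%, 92.5% and 100% of 67 genes changed 1.5-fold, 2-fold and 4-fold, with 5 false calls among 173. For the difference in genotype effect between proestrus and diestrus it recovered 25.4%, 73.1% and 97% of 67 genes at the same sizes, with 6 false calls among 137. An unchanged contrast gave 0 calls.

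Alternatives were DESeq2 1.42.0, edgeR with median-of-ratios (RLE) size factors, limma voom with sample quality weights, no low-count filter, a fit to the compared groups only, the replicate number as a block, the number in the library name as a factor, X and Y genes left out of the counts, and each library left out in turn. Chosen after the data were seen were a fit without 3 libraries that stand apart (diestrus BL6 replicate 1, male 5xFAD replicate 1 and male BL6 replicate 4), X and Y genes left out before the adjustment, contrasts averaged over genotypes, and the permutation tests of list levels. Male BL6 replicate 4 did not stand apart on the second principal component (5.5). It lay above its group in the level of glucocorticoid targets (4.87 against 3.5 to 3.6). Plots were drawn with matplotlib 3.10.9 (Python 3.11.15).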

Results

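Microglia, the resident macrophages of the brain, were profiled from the cortex of mice at 5.5 months to ask how sex and the oestrous cycle bear on their response in a mouse model of amyloid deposition. 5xFAD mice carry human transgenes with familial Alzheimer's disease mutations under mouse Thy1 elements and deposit amyloid-beta in the brain, and C57BL6/J (BL6) mice were the controls. Females had been staged by vaginal smears over 2 weeks and by uterine weight as proestrus, when oestradiol is high, or diestrus, when it is low. Each of the 6 groups held 4 libraries. Total counts averaged 56.3 M ± 9.29 in proestrus BL6, 53.8 M ± 6.15 in proestrus 5xFAD, 51.2 M ± 5.64 in diestrus BL6, 53.1 M ± 2.68 in diestrus 5xFAD, 55.5 M ± 6.96 in male BL6 and 63.7 M ± 7.9 in male 5xFAD (SD, n = 4 each). Between 20600 and 23783 genes had a count in a library.

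The libraries carried the marks of microglia and of the labelled sexes. Tmem119, a microglial surface protein, stood at 7500 ± 503 CPM in proestrus BL6, 7810 ± 1180 in diestrus BL6 and 7300 ± 566 in male BL6 (SD, n = 4). Xist, the RNA that silences 1 X chromosome in females, averaged 173 ± 33.9 CPM in proestrus BL6, 160 ± 6.89 in proestrus 5xFAD, 175 ± 62.4 in diestrus BL6 and 153 ± 20.6 in diestrus 5xFAD, and did not exceed 0.276 CPM in any male library (SD, n = 4). The Y-linked helicase Ddx3y averaged 81 ± 5.58 CPM in male BL6 and 76.2 ± 8.49 in male 5xFAD (SD, n = 4), and among females it had counts in diestrus BL6 replicate 4 alone, at 0.196 CPM. App averaged 186 ± 22.8, 202 ± 42.1 and 176 ± 18.4 CPM in proestrus, diestrus and male BL6, against 220 ± 30.3, 259 ± 23.4 and 199 ± 15.5 in 5xFAD (SD, n = 4). Thy1 stayed near 0, with at most 0.611 CPM. Whether human transgene reads were counted under mouse symbols is not given in the sources used here.

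Markers of several other cell types were low, and the higher sums of the rest rested on few genes, whose cell of origin was not tested. The neuron list summed to between 14.2 ± 5.44 CPM in proestrus 5xFAD and 23.5 ± 7.36 in male BL6 (SD, n = 4), led by Meg3 at 6.25 CPM over the 24 libraries. Monocyte markers summed to 10.9 to 19 CPM (Ccr2 6.67), oligodendrocyte precursor markers to 1.19 to 5.6 CPM (Cspg4 2.03), T and NK cell markers to 1.19 to 9.22 CPM (Ccl5 3.39) and haemoglobin and other erythrocyte genes to 1.21 to 8.01 CPM (Hbb-bs 1.67). The most abundant members of the higher sums were Stab1 (526 CPM) for border macrophages, Csf3r (833 CPM) for neutrophils, Ighm (625 CPM) for B cells, Slc1a3 (263 CPM) for astrocytes, Cnp (122 CPM) and Mag (45.9 CPM) for oligodendrocytes and Pecam1 (31.1 CPM) for the endothelium and mural cells. Neutrophil markers varied between libraries of every group, with an SD of the list level of 1.84 to 2.31 (n = 4). In proestrus BL6 that level ran from -2.85 to 2.37. Ngp, another neutrophil marker, averaged 5.1 ± 6.61 CPM (SD, 24 libraries). The first principal component held 17.3% of the variance and put all 12 5xFAD libraries (3.5 to 67.7) above all 12 BL6 libraries (-50.3 to -13.7). On the second, with 7.1%, diestrus BL6 replicate 1 (74.7) and male 5xFAD replicate 1 (56.8) stood apart.

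**Figure D1:**
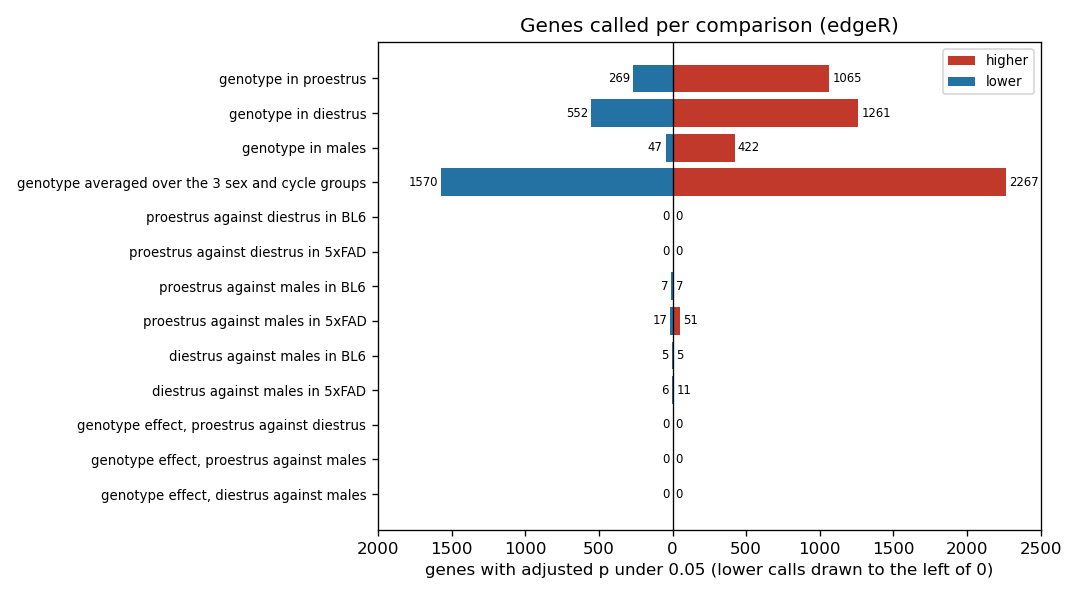
Number of genes called in each of the 13 comparisons by edgeR at an adjusted p under 0.05, with genes higher in the group named first (5xFAD for genotype) drawn to the right of 0, those lower to the left, and each number printed beside its bar. Genotype gave 1334, 1813 and 469 genes within the 3 sex and cycle groups, while proestrus against diestrus and the differences between genotype effects gave 0.

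In proestrus females, 5xFAD microglia took up the disease-associated (DAM) programme, the gene set of microglia that gather at plaques. Of its 40 members, 38 rose (38 adjusted over the list alone, where 1 also fell), with a median log2 fold change of 1.96. Cst7, an inhibitor of lysosomal cathepsins, rose from 11.2 ± 0.554 to 986 ± 422 CPM (SD, n = 4). Apoe, the main lipid carrier of the brain, rose from 437 ± 147 to 5340 ± 1820 CPM. Lipoprotein lipase Lpl rose by 4.33 ± 0.3 (log2, SE), the glucan receptor Clec7a by 4.14 ± 0.31, the integrin Itgax by 3.36 ± 0.34 and the secreted phosphoprotein Spp1 by 3.37 ± 0.61, at edgeR adjusted p of 7.43e-09, 1.74e-08, 4.81e-07 and 9e-04. Trem2, the lipid-sensing receptor that the programme depends on, rose less, by 0.59 ± 0.1 (edgeR adjusted p = 0.000198).

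Several of the highest fold changes taken by the naming rule in proestrus belonged to genes almost silent in BL6. Mamdc2 went from 0 CPM in all 4 BL6 libraries to 8.4 ± 4.15 in 5xFAD, the heparan sulphate-cutting enzyme Hpse from 0.0205 to 21.1 ± 12.6, Lgi2 from 0.0801 to 21.5 ± 16.4, Baiap2l2 from 0.291 to 53.6 ± 24.9 and the growth factor Igf1 from 0.204 to 34.2 ± 15.2 (SD, n = 4). The panel gene Gpnmb, with a smaller fold change than these, went from 0.559 to 16.4 ± 15.7 CPM (SD, n = 4). At the other end of the genes taken by the naming rule were the prostaglandin E2 receptor Ptger3 (-1.21 ± 0.28, edgeR adjusted p = 0.00541), Apobec2 (-1.21 ± 0.27), the X-linked orphan receptor Gpr165 (-1.18 ± 0.21), adenylate cyclase Adcy8 (-1.1 ± 0.33), the integrin Itgae (-1.09 ± 0.2) and Gng7 (-0.97 ± 0.25). Of the homeostatic genes, 5 of 24 fell (10 adjusted over the list alone). Among them the transcription factors Maf (-0.49 ± 0.1) and Sall1 (-0.32 ± 0.09) and the surface protein Tmem119 (-0.29 ± 0.09) passed at edgeR adjusted p of 0.00127, 0.0255 and 0.0471. The purinergic receptor P2ry12 (-0.34 ± 0.12, 0.105) and the fractalkine receptor Cx3cr1 (-0.31 ± 0.1, 0.0689) did not pass edgeR's test. The list's lower position (camera adjusted p = 0.000207) was lost at an adjusted p = 0.37 with an estimated correlation.

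Immune programmes rose with the DAM genes in proestrus. Of the interferon-response genes 32 of 36 rose (36 adjusted over the list alone, median 2.13), such as Ifi27l2a (3.93 ± 0.4), the antiviral Oasl2 (3.41 ± 0.41) and Ifitm3 (3.37 ± 0.4). Antigen presentation moved too: 11 of 15 genes of class I and peptide loading rose (13 adjusted over the list alone), among them H2-D1 (1.52 ± 0.19) and B2m (1.09 ± 0.15), and 6 of 10 class II genes (6 adjusted over the list alone), led by the invariant chain Cd74 (1.93 ± 0.28). Of 28 inflammatory genes 10 rose and 1 fell (11 and 2 adjusted over the list alone), with the chemokines Ccl4 (2.4 ± 0.2) and Ccl3 (2.8 ± 0.31) at the smallest p. Among phagocytic and amyloid receptors 9 of 23 rose and 1 fell (13 and 1 adjusted over the list alone), including the receptor kinase Axl (4.32 ± 0.4). Camera with an estimated correlation called all 5 of these lists. Complement genes rose in 4 of 16 cases (5 adjusted over the list alone), among them C3 (3.79 ± 0.81), and that list's call was lost at an adjusted p = 0.163 with an estimated correlation.

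Proliferation, lipid handling and metabolism followed in proestrus. Cell cycle genes rose in 20 of 35 cases (27 adjusted over the list alone), as with the mitotic kinase Cdk1 (1.8 ± 0.23) and the replication helicase subunit Mcm2 (1.48 ± 0.23). Cytosolic ribosomal proteins rose in 75 of 79 cases and 1 fell (the same counts adjusted over the list alone), with a median of 0.73. Of glycolysis genes 12 of 20 rose and 1 fell (14 and 1 adjusted over the list alone), led by Tpi1 (1.12 ± 0.12) and Pkm (1.24 ± 0.14). Oxidative phosphorylation genes rose in 34 of 75 cases (53 adjusted over the list alone, median 0.31), led by Ndufa1 (1.53 ± 0.18). Lysosomal genes rose in 22 of 36 cases (25 adjusted over the list alone), lipid uptake, storage and efflux genes in 10 of 27 (16), and cholesterol synthesis genes in 10 of 23 (12), with the sterol sensor Insig1 at 1.43 ± 0.19. All 7 lists were called with an estimated correlation. Mitochondrially encoded genes rose in 3 of 9 cases (6 adjusted over the list alone), a call lost at an adjusted p = 0.163 with an estimated correlation. Immediate early genes rose in 3 of 24 cases (3 adjusted over the list alone), Egr2 (2.86 ± 0.44), Egr1 (1.59 ± 0.26) and Atf3 (1.06 ± 0.21), and this list's call was lost at an adjusted p = 0.36 with an estimated correlation.

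By edgeR's quasi-likelihood test 1334 genes were called in proestrus at a Benjamini-Hochberg adjusted p under 0.05, with 1065 higher and 269 lower in 5xFAD. Of these 375 rose and 36 fell at least 2-fold. Without proestrus 5xFAD replicate 3 the count was 793. Steroid receptor, glucocorticoid, circadian clock, TGF-beta and sex chromosome lists were not called. The glucocorticoid target Cdkn1a (1.69 ± 0.18), a cell cycle inhibitor, and Bhlhe40, a repressor of the clock, at 0.771 ± 0.647 CPM in BL6 and 33.6 ± 16.3 in 5xFAD (SD, n = 4), rose within them. Neuron markers lay lower in 5xFAD (camera adjusted p = 0.0172), a call lost at an adjusted p = 0.241 with an estimated correlation, and Snap25 was at 2.72 ± 0.588 CPM in BL6 and 0.607 ± 0.226 in 5xFAD (SD, n = 4). Oligodendrocyte markers likewise lay lower (camera adjusted p = 0.0482), which became an adjusted p = 0.514 with an estimated correlation. None of the other 9 lists of other cells was called. Within those, Gfap (0.12 ± 0.164 to 2.11 ± 0.99 CPM), Cspg4 (0.0497 ± 0.0746 to 4.81 ± 2.97) and Flt1 (0.183 ± 0.259 to 5.27 ± 4.48) rose.

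In diestrus females the same comparison gave the DAM programme again, with 38 of 40 members higher (39 adjusted over the list alone, median 2.21). Cst7 rose from 10.3 ± 2.68 to 1020 ± 101 CPM and Apoe from 358 ± 71.1 to 5110 ± 550 CPM (SD, n = 4). Lpl (4.53 ± 0.3), Clec7a (4.4 ± 0.32), Itgax (3.46 ± 0.34), Spp1 (3.93 ± 0.63) and Trem2 (0.61 ± 0.1) all rose, at edgeR adjusted p of 3.59e-09, 7.86e-09, 2.54e-07, 0.000195 and 0.000107. Genes almost silent in BL6 again led those taken by the naming rule: Dcstamp, a cell fusion protein, went from 0 to 11.4 ± 4.22 CPM, Mamdc2 from 0 to 11.4 ± 1.29, Hpse from 0.0104 to 16.1 ± 3.76, Lgi2 from 0.0139 to 17 ± 3.5, Baiap2l2 from 0.0876 to 53.3 ± 4.6 and Gpnmb from 0.0148 to 13.7 ± 6.61 (SD, n = 4).

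Homeostatic genes fell in 8 of 24 cases in diestrus (11 adjusted over the list alone, median -0.24). Maf (-0.54 ± 0.1), Tmem119 (-0.42 ± 0.09), Cx3cr1 (-0.45 ± 0.1) and Sall1 (-0.39 ± 0.09) passed at edgeR adjusted p of 0.000359, 0.00228, 0.00449 and 0.0041, and P2ry12 (-0.35 ± 0.12) did not, at 0.0789. As a list (camera adjusted p = 1.76e-05) the call was lost at an adjusted p = 0.311 with an estimated correlation. Of the genes taken by the naming rule, the lowest fold changes were those of Ptger3 (-1.32 ± 0.28), the clock-output factor Hlf (-1.21 ± 0.21), Fgf11 (-1.12 ± 0.25), Mycl (-1.04 ± 0.21), Sema4b (-1.03 ± 0.19) and Gpr165 (-1.03 ± 0.21). The glucocorticoid receptor Nr3c1 fell by 0.27 ± 0.08 on the log2 scale (edgeR adjusted p = 0.0275).

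Immune and growth programmes rose in diestrus as well. Interferon-response genes rose in 34 of 36 cases (36 adjusted over the list alone, median 2.28), class I and peptide loading genes in 12 of 15 (12), class II genes in 5 of 10 (6), and cell cycle genes in 27 of 35 (33 adjusted over the list alone, median 1.84). Ifi27l2a (4.49 ± 0.42), H2-Q6 (3.14 ± 0.38), Cd74 (1.58 ± 0.27) and Cdk1 (2.51 ± 0.24) were among them. Of inflammatory genes 14 of 28 rose and 1 fell (17 and 1 adjusted over the list alone), and of phagocytic and amyloid receptors 8 of 23 rose and 2 fell (10 and 2 adjusted over the list alone). Ribosomal proteins rose in 75 of 79 cases (76 adjusted over the list alone, median 0.72), glycolysis genes in 12 of 20 (14), lysosomal genes in 25 of 36 (28 and 1 fall adjusted over the list alone), lipid genes in 12 of 27 (15 and 2 falls) and cholesterol synthesis genes in 13 of 23 (15). Mitochondrially encoded genes rose in 7 of 9 cases (8 adjusted over the list alone), with mt-Co1 at 1 ± 0.14. All of these were called with an estimated correlation.

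Other lists in diestrus were weaker. Oxidative phosphorylation genes rose in 40 of 75 cases (48 adjusted over the list alone), and the call was lost at an adjusted p = 0.065 with an estimated correlation. Complement genes rose in 5 of 16 cases (5 adjusted over the list alone), with an adjusted p = 0.136 with an estimated correlation. T and NK cell markers rose in 2 of 4 cases (2 adjusted over the list alone), namely Klrb1c (0.03 ± 0.06 to 1.57 ± 0.907 CPM) and the chemokine Ccl5 (0.769 ± 0.507 to 4.97 ± 2.28 CPM; SD, n = 4). That call was lost at an adjusted p = 0.065 with an estimated correlation. The immediate early, steroid receptor, glucocorticoid, circadian, TGF-beta and sex chromosome lists and the other 10 lists of other cells were not called. In all 1813 genes were called by edgeR, 1261 higher and 552 lower in 5xFAD, of which 476 and 57 changed at least 2-fold. Fitted to the diestrus libraries only, the model called 1166.

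Male 5xFAD microglia also took up the DAM programme, with 38 of 40 members higher (38 adjusted over the list alone, median 1.61), while homeostatic genes stayed close to BL6. Cst7 rose from 10.2 ± 1.84 to 601 ± 406 CPM and Apoe from 356 ± 83.1 to 2620 ± 1570 CPM (SD, n = 4). Male 5xFAD libraries spread widely: Cst7 stood at 302, 1090, 236 and 776 CPM in replicates 1 to 4. Lpl (3.86 ± 0.29), Clec7a (3.47 ± 0.3), Itgax (3.06 ± 0.34), Spp1 (3.6 ± 0.63) and Trem2 (0.37 ± 0.1) rose at edgeR adjusted p of 5.44e-08, 3.33e-07, 4.69e-06, 0.00204 and 0.0422. Among genes near 0 in BL6, Mamdc2 reached 7.12 ± 5.98 CPM, Lgi2 5.4 ± 4.49, Dcstamp 5.3 ± 4.32, Baiap2l2 31.5 ± 16.8 and Gpnmb 4.53 ± 5.78 (SD, n = 4).

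In males 0 of 24 homeostatic genes were called (0 adjusted over the list alone; edgeR). P2ry12 (0.05 ± 0.12), Tmem119 (-0.11 ± 0.09), Cx3cr1 (-0.12 ± 0.1) and Sall1 (-0.15 ± 0.09) had edgeR adjusted p of 0.908, 0.625, 0.67 and 0.469. Of the genes taken by the naming rule, with its limits on level and overlap, the lowest fold changes were those of Cep72 (-1.13 ± 0.27), the cytoskeletal linker Utrn (-0.75 ± 0.18), the chromatin remodelling subunits Ino80d (-0.75 ± 0.14) and Srcap (-0.7 ± 0.17), Ralgapa2 (-0.74 ± 0.2) and Adat1 (-0.64 ± 0.18). Other called genes fell further. Interferon-response genes rose in 15 of 36 cases (25 adjusted over the list alone, median 1.16), class I and peptide loading genes in 4 of 15 (9), class II genes in 3 of 10 (6), cell cycle genes in 8 of 35 (15) and inflammatory genes in 6 of 28 (10). Ifi27l2a (3.07 ± 0.4), H2-D1 (1.11 ± 0.18), Cd74 (1.42 ± 0.27), Cdk1 (1.24 ± 0.23) and Ccl4 (2 ± 0.2) were examples.

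Ribosomal proteins rose in 42 of 79 cases in males (71 adjusted over the list alone, median 0.43), glycolysis genes in 12 of 20 (12), lysosomal genes in 17 of 36 (27), lipid genes in 8 of 27 (14), cholesterol synthesis genes in 8 of 23 (13), phagocytic and amyloid receptors in 6 of 23 (9), complement genes in 2 of 16 (4) and immediate early genes in 5 of 24 (6). Rps26 (0.67 ± 0.11), Pkm (0.85 ± 0.14), Cd63 (0.88 ± 0.13), Insig1 (1 ± 0.19) and Axl (3.95 ± 0.4) were examples. These lists were called with an estimated correlation. Beside the immediate early list stands the level of that list in male 5xFAD replicate 1, at 5.27 against 4.38 to 4.84 in the other 3 libraries. Oxidative phosphorylation genes rose in 8 of 75 cases (36 adjusted over the list alone), with an adjusted p = 0.0747 with an estimated correlation, and mitochondrially encoded genes in 3 of 9 (5 adjusted over the list alone), with an adjusted p = 0.113 with an estimated correlation.

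The TGF-beta list had 0 of 17 members called in males (0 adjusted over the list alone; edgeR). Its higher position (camera adjusted p = 0.0481) was lost at an adjusted p = 0.501 with an estimated correlation. Astrocyte markers lay lower (camera adjusted p = 0.0458, 0.142 as adjusted p with an estimated correlation). T and NK cell markers lay higher (camera adjusted p = 0.037), which became an adjusted p = 0.0728 with an estimated correlation. The steroid receptor, glucocorticoid, circadian and sex chromosome lists and the other 9 lists of other cells were not called. In all edgeR called 469 genes in males, 422 higher and 47 lower in 5xFAD, of which 178 and 16 changed at least 2-fold, and DESeq2 called 780. The edgeR count was 224 without male 5xFAD replicate 2, 235 without its replicate 4, 301 without male BL6 replicate 2 and 278 without male BL6 replicate 3.

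**Figure D2:**
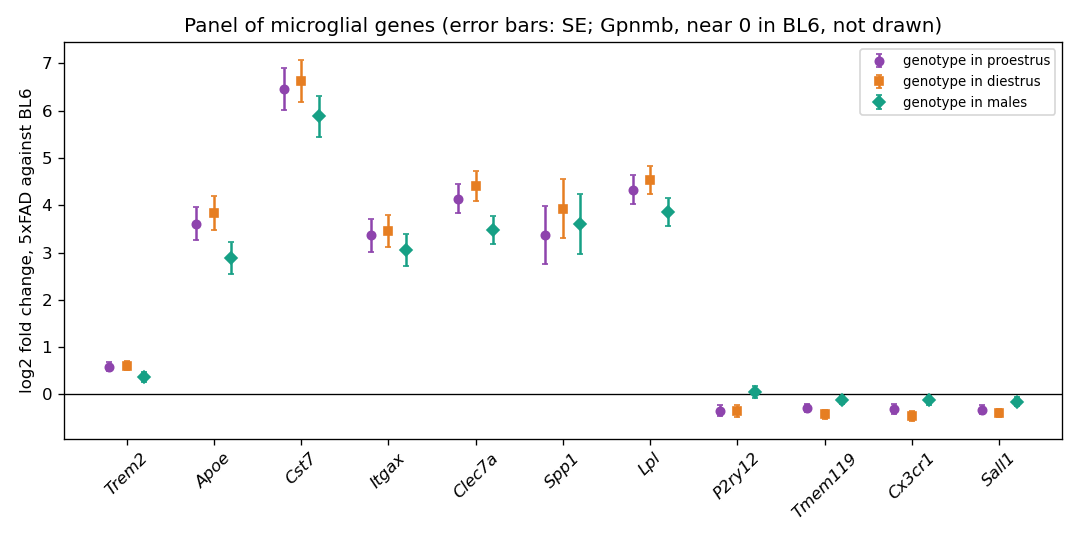
Log2 fold change of 5xFAD against BL6 (vertical axis) for 11 genes of the panel fixed beforehand, in proestrus (circles), diestrus (squares) and males (diamonds), with bars for the standard error from edgeR. Cst7 stands at 6.46, 6.62 and 5.88, and P2ry12, Tmem119, Cx3cr1 and Sall1 lie between -0.45 and 0.05.

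Averaged over proestrus, diestrus and males, 5xFAD microglia took up the DAM programme, with 38 of 40 members higher (39 higher and 1 lower adjusted over the list alone, median 1.93). Cst7 rose by 6.32 ± 0.25, Lpl by 4.24 ± 0.17, Clec7a by 4 ± 0.18, Apoe by 3.44 ± 0.2, Spp1 by 3.63 ± 0.36, Itgax by 3.29 ± 0.2 and Trem2 by 0.52 ± 0.06 (log2, SE), with edgeR adjusted p of 1.21e-07 or below. Of the homeostatic genes 10 of 24 fell (11 lower and 2 higher adjusted over the list alone, median -0.11), among them P2ry12 (-0.21 ± 0.07), Tmem119 (-0.27 ± 0.05), Cx3cr1 (-0.29 ± 0.06) and Sall1 (-0.28 ± 0.05), at edgeR adjusted p of 0.0344, 0.000291, 0.000695 and 0.000168, where males alone had 0 called by edgeR and a median of 0. All 36 interferon-response genes rose (36 adjusted over the list alone), as did 33 of 35 cell cycle genes (34 adjusted over the list alone) and 76 of 79 ribosomal proteins, with 1 ribosomal protein lower (77 and 1 adjusted over the list alone). In this contrast 3837 genes were called by edgeR, 2267 higher and 1570 lower. Of the lists called by camera, 13 of 19 in proestrus, 13 of 17 in diestrus, 14 of 19 in males and 13 of 18 in the average held with an estimated correlation. The calls lost in the average were those of homeostatic, immediate early, mitochondrially encoded and complement genes and T and NK cell markers, with an adjusted p of 0.499, 0.206, 0.0589, 0.0634 and 0.0565 with an estimated correlation.

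The genotype responses of the 3 groups shared many genes. Genes called higher in 5xFAD, such as Apoe, Cst7 and Lpl, numbered 387 in all 3 groups, against 1.65 for independent lists. Pairwise, 891 were shared by proestrus and diestrus (72.4 for independent lists), 389 by proestrus and males (24.2) and 408 by diestrus and males (28.7). Of genes called lower, 130 were shared by proestrus and diestrus (8.01), 5 by proestrus and males (0.682), 14 by diestrus and males (1.4) and 4 by all 3 (0.0203). No gene was called in opposite directions in a pair of groups by edgeR. By DESeq2 536 genes were shared by all 3 groups in the same direction, against 391 by edgeR. Of the genes called in proestrus, 96.6% had the same sign in males. Their median signed change was 0.36 in males and 0.6 in diestrus, against 0.64 in proestrus, where they were selected. Selection by calls tends to raise the median of the group in which genes were called. Of those called in males, 97.9% had the same sign in proestrus and 98.9% in diestrus, with medians of 0.89 and 0.97 there against 0.76 in males. The 3 comparisons share no library.

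Between proestrus and diestrus, no gene passed edgeR's test in either genotype. In the simulated genotype comparison, also of 4 against 4 libraries, 58.2% of genes changed 1.5-fold were recovered, so differences of that size could be missed. In BL6 the genes with the smallest p were the RNA polymerase II-associated factor Scaf8 (-0.59 ± 0.1, edgeR adjusted p = 0.0631) and the zinc finger gene Zfp354c (-1.08 ± 0.2, edgeR adjusted p = 0.107), neither of which passed. In 5xFAD they were the ubiquitin ligase Smurf2 (-0.51 ± 0.1), N4bp3 (1.82 ± 0.38) and the inflammasome sensor Nlrp3 (0.52 ± 0.11), with edgeR adjusted p of 0.43, 0.616 and 0.626. Esr1, the oestrogen receptor alpha gene, stood at 8.59 ± 2.63 CPM in proestrus BL6, 7.98 ± 1.29 in diestrus BL6, 8.2 ± 2.08 in proestrus 5xFAD, 9.81 ± 3.33 in diestrus 5xFAD, 7.44 ± 2.39 in male BL6 and 7.47 ± 2.33 in male 5xFAD (SD, n = 4). Esr2 and Pgr, the genes of oestrogen receptor beta and of the progesterone receptor, did not exceed 0.0184 and 0.349 CPM in any library. The membrane oestrogen receptor Gper1 averaged 0.0922 to 1.97 CPM over the groups.

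Of the lists, interferon-response genes lay higher in proestrus in both genotypes (median 0.4 in BL6 and 0.32 in 5xFAD), with 0 of 36 members called by edgeR (4 adjusted over the list alone in BL6 and 0 in 5xFAD). The calls (camera adjusted p = 7.73e-06 and 3.73e-05) were lost at an adjusted p = 0.812 and an adjusted p = 0.991 with an estimated correlation. In BL6 camera also called class I genes, oxidative phosphorylation and ribosomal proteins higher and sex chromosome genes lower in proestrus, with medians of 0.1, 0.07, 0.08 and -0.17 (the last -0.06 with genes at 0 in a group set to their bound). In 5xFAD it called class I genes (0.12), oxidative phosphorylation (0.07) and ribosomal proteins (0.07) higher and DAM genes (-0.08), the cell cycle (-0.32), mitochondrially encoded genes (-0.2) and lysosomal genes (-0.07) lower. With an estimated correlation none of the 5 lists in BL6 or the 8 in 5xFAD was called, at adjusted p of 0.812 or more in BL6 and 0.991 or more in 5xFAD. edgeR called 0 of 18546 genes in either genotype, with 1286 genes in BL6 and 1164 in 5xFAD at an unadjusted p under 0.05, against 927 by chance. DESeq2 called 14 in BL6 and 10 in 5xFAD, and limma voom 1 and 0. Without proestrus BL6 replicate 3 or replicate 4, edgeR called 2 genes and 1 gene in BL6.

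Proestrus females and males of the BL6 strain differed in a small set of autosomal genes. In this and the other comparisons of females with males, no number in the library names held both sexes. Outside the sex chromosomes, sex and that number cannot be told apart. Gpx1, glutathione peroxidase 1, was higher in females at 103 ± 2.56 against 62.9 ± 5.87 CPM (SD, n = 4; 0.71 ± 0.09, edgeR adjusted p = 6.11e-05). The selenoprotein gene Selenow (0.8 ± 0.13), Nlrp3 (0.81 ± 0.11), the calcium channel Trpv4 (1.53 ± 0.24) and N4bp3 (1.94 ± 0.38) were also higher, at edgeR adjusted p of 0.00424, 0.000434, 0.00213 and 0.042. Zfp354c (-1.35 ± 0.2) and the nuclear matrix protein Banp (-0.65 ± 0.13) were lower, at 0.00119 and 0.0322 by edgeR. Of the sex chromosome list, Xist and Tsix were higher and Ddx3y, Eif2s3y, Kdm5d and Uty lower in females. The X-linked genes Kdm6a (0.58 ± 0.17), Eif2s3x (0.59 ± 0.14), Ddx3x (0.25 ± 0.11) and Kdm5c (0.33 ± 0.09) did not pass over all genes, and 6 members were higher and 4 lower adjusted over the list alone. The list's test pointed down and was called with an estimated correlation, while its median was 0.29 and its mean -3.67.

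In this comparison the interferon, class I and ribosomal lists lay higher in proestrus (medians 0.35, 0.13 and 0.06) with 0 members called by edgeR (0 adjusted over the list alone). Their calls were lost at an adjusted p = 0.893 with an estimated correlation. edgeR called 14 genes, 7 higher and 7 lower in proestrus, and 7 lay outside the X and Y chromosomes. With X and Y genes left out before the adjustment 5 were called by edgeR, without Banp (edgeR adjusted p = 0.0677) and N4bp3 (edgeR adjusted p = 0.0817). DESeq2 called 81 and limma voom 27. In diestrus against male BL6, edgeR called 10 genes, and Gpx1 was the 1 outside the X and Y chromosomes (95.3 ± 7.43 CPM in diestrus, SD, n = 4; 0.6 ± 0.09, edgeR adjusted p = 0.00111). Eif2s3x (0.75 ± 0.14) and Kdm5c (0.57 ± 0.09), which escape X inactivation, were also higher in diestrus at edgeR adjusted p of 0.0262 and 0.00569. The sex chromosome list (4 higher and 4 lower, 6 and 4 adjusted over the list alone) was called with an estimated correlation, pointing down by its test with a median of 0.46. Oxidative phosphorylation genes lay lower (median -0.07, camera adjusted p = 0.0116), which became an adjusted p = 0.991 with an estimated correlation.

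In 5xFAD, proestrus microglia on average expressed interferon-response genes more highly than male microglia. The list level of single libraries ran from 4.46 to 5.81 in proestrus and from 3.37 to 4.54 in males, so the groups overlapped. The interferon-induced genes Ifi27l2a (106 ± 48.8 against 30.5 ± 13.4 CPM) and Ifit3 (96.9 ± 52.2 against 30 ± 10.8 CPM) and the class I gene H2-Q6 (8.84 ± 3.16 against 2.95 ± 0.394 CPM; SD, n = 4) were higher by 1.8 ± 0.37, 1.69 ± 0.34 and 1.58 ± 0.36, at edgeR adjusted p of 0.0297, 0.0274 and 0.0467. Ifi209 (1.46 ± 0.31) and the class I transactivator Nlrc5 (1.42 ± 0.3) followed. Of the interferon list 19 of 36 members were higher (34 adjusted over the list alone, median 1.37), including Sp100 (1.3 ± 0.22) and Xaf1 (1 ± 0.18), and the call held with an estimated correlation (adjusted p = 0.0353). Slco4a1 (-0.79 ± 0.16), Fchsd2 (-0.55 ± 0.1), the haem synthesis enzyme Cpox (-0.49 ± 0.09), Smurf2 (-0.48 ± 0.1) and Stxbp3 (-0.46 ± 0.09) were lowest of the genes taken by the naming rule.

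Other lists of that comparison were called only with the preset correlation, apart from the sex chromosome genes (4 higher, 4 lower, 6 and 4 adjusted over the list alone). Class I genes were higher in 4 of 15 cases (10 adjusted over the list alone), with an adjusted p = 0.0623 with an estimated correlation. Ribosomal proteins were higher in 4 of 79 cases (74 adjusted over the list alone, median 0.37), with an adjusted p = 0.0896 with an estimated correlation. Immediate early genes lay lower (median -0.44), with 0 members called by edgeR and 9 lower adjusted over the list alone, and an adjusted p = 0.192 with an estimated correlation. In male 5xFAD replicate 1 the immediate early gene Fos reached 37.3 CPM, against 1.89 CPM or less in the proestrus 5xFAD libraries. DAM genes (median 0.41) had 0 of 40 members called by edgeR and 8 higher adjusted over the list alone, with an adjusted p = 0.238 with an estimated correlation. Class II, cell cycle, glycolysis, oxidative phosphorylation, cholesterol, lipid and lysosomal lists lay higher and homeostatic, TGF-beta and neuron lists lower, all with an adjusted p of 0.192 or more with an estimated correlation.

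edgeR called 68 genes between proestrus and male 5xFAD microglia, 51 higher and 17 lower in proestrus, and 55 of them lay outside the X and Y chromosomes. With X and Y genes left out before the adjustment edgeR called 35, and H2-Q6 was among those lost (edgeR adjusted p = 0.0559). The count depended on the fit: DESeq2 gave 267, limma voom 104, no low-count filter 35, a fit to these groups only 10, and the fit without the 3 libraries that stand apart 24. It was 12, 21, 16, 125, 13 and 32 without proestrus 5xFAD replicate 3, proestrus 5xFAD replicate 1, and male 5xFAD replicates 1, 2, 3 and 4.

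Diestrus 5xFAD microglia were higher than male ones in the antioxidant enzyme gene Gpx1. Gpx1 averaged 115 ± 6.37 CPM in diestrus and 73.9 ± 11.1 in males (SD, n = 4; 0.64 ± 0.09, edgeR adjusted p = 3e-04). Tpi1 (0.66 ± 0.12), Gapdh (0.64 ± 0.12) and the X-linked Pgk1 (0.7 ± 0.12), which act in successive steps of glycolysis, were higher at edgeR adjusted p of 0.0158, 0.0294 and 0.0129. The glycolysis list had 3 of 20 members higher (10 adjusted over the list alone), with an adjusted p = 0.0877 with an estimated correlation. The translation elongation factor Eef1a1 (0.62 ± 0.11) and the interferon-induced nuclear body gene Sp100 (1.1 ± 0.22) were higher and Sgsm3 (-0.39 ± 0.08) was lower. Eif2s3x (1.14 ± 0.14) and Ddx3x (0.53 ± 0.11) were higher too. The remaining called gene outside X and Y was a predicted one.

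Interferon-response genes were higher in 1 of 36 cases (30 adjusted over the list alone, median 1.04) and DAM genes in 0 of 40 by edgeR (25 adjusted over the list alone, median 0.59), each with an adjusted p = 0.119 with an estimated correlation. Ribosomal proteins were higher in 0 of 79 cases by edgeR (43 adjusted over the list alone), with an adjusted p = 0.167 with an estimated correlation. Cell cycle, class I and II, inflammatory, mitochondrially encoded, cholesterol, lipid and lysosomal lists lay higher and homeostatic, immediate early and TGF-beta lists lower, with an adjusted p of 0.134 or more with an estimated correlation. The sex chromosome list (4 higher and 4 lower, 6 and 4 adjusted over the list alone) was called under both settings. edgeR called 17 genes, 11 higher and 6 lower, and 7 outside the X and Y chromosomes. With X and Y genes left out before the adjustment edgeR called Gpx1 alone (edgeR adjusted p = 0.00262), and Tpi1, Eef1a1, Gapdh, Sp100 and Sgsm3 had edgeR adjusted p of 0.0772, 0.0772, 0.0929, 0.102 and 0.102. Over all genes DESeq2 called 231 and limma voom 141. The edgeR count was 11 without diestrus 5xFAD replicate 1, 48 without its replicate 4, and 11, 53 and 9 without male 5xFAD replicates 1, 2 and 3.

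**Figure D3:**
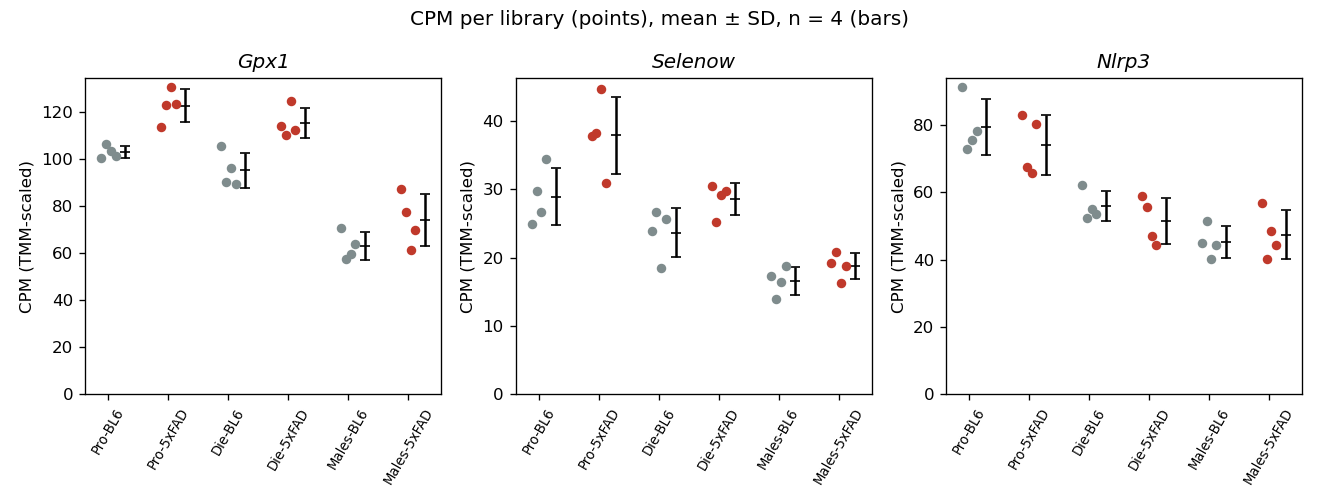
TMM-scaled CPM of Gpx1, Selenow and Nlrp3 (vertical axes) in each of the 24 libraries by group, BL6 in grey and 5xFAD in red, with the mean and SD of the 4 libraries beside the points. Mean Gpx1 is 103 and 95.3 CPM in BL6 females against 62.9 in BL6 males, and mean Nlrp3 is 79.4 in proestrus BL6 against 55.9 in diestrus BL6 and 45.2 in male BL6.

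The differences between genotype effects asked directly whether sex or cycle stage altered the genotype effect, and no single gene passed. Between proestrus and diestrus the smallest p belonged to Ep300, a histone acetyltransferase (0.54 ± 0.11, edgeR adjusted p = 0.902), followed by a predicted gene and Ptgs2, which are near 0 CPM in some groups. Between proestrus and males they belonged to Utrn (1.29 ± 0.25, edgeR adjusted p = 0.549), the nuclear lamina gene Lmna (1.26 ± 0.28, edgeR adjusted p = 0.81) and a predicted gene near 0 CPM. Between diestrus and males they belonged to Stard8 (-0.73 ± 0.15), Angptl7 (-0.72 ± 0.17) and H2-Q6 (2.2 ± 0.51), each at an edgeR adjusted p of 0.586. edgeR called 0 genes in each of the 3, with 640, 873 and 1083 genes at an unadjusted p under 0.05 against 927 by chance. DESeq2 called 2, 5 and 1, limma voom 0 in each, and edgeR called 1 gene between proestrus and males without proestrus 5xFAD replicate 1.

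As lists, interferon-response genes had the largest shift between the sexes of the lists called. Their genotype effect was larger in proestrus than in males by a median of 0.77 (camera adjusted p = 3.67e-24, with 0 of 36 members called by edgeR and 17 adjusted over the list alone) and larger in diestrus than in males by 0.98 (camera adjusted p = 2.18e-23, 0 and 7 members). These calls were lost at an adjusted p = 0.519 and an adjusted p = 0.301 with an estimated correlation. DAM genes had a larger effect by 0.31 in proestrus and 0.47 in diestrus than in males, with 0 of 40 members called by edgeR (0 and 1 adjusted over the list alone), also lost at an adjusted p = 0.519 and an adjusted p = 0.301 with an estimated correlation. With an estimated correlation no list was called in any of the 3 differences, where the preset correlation called 2, 10 and 14.

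**Figure D4:**
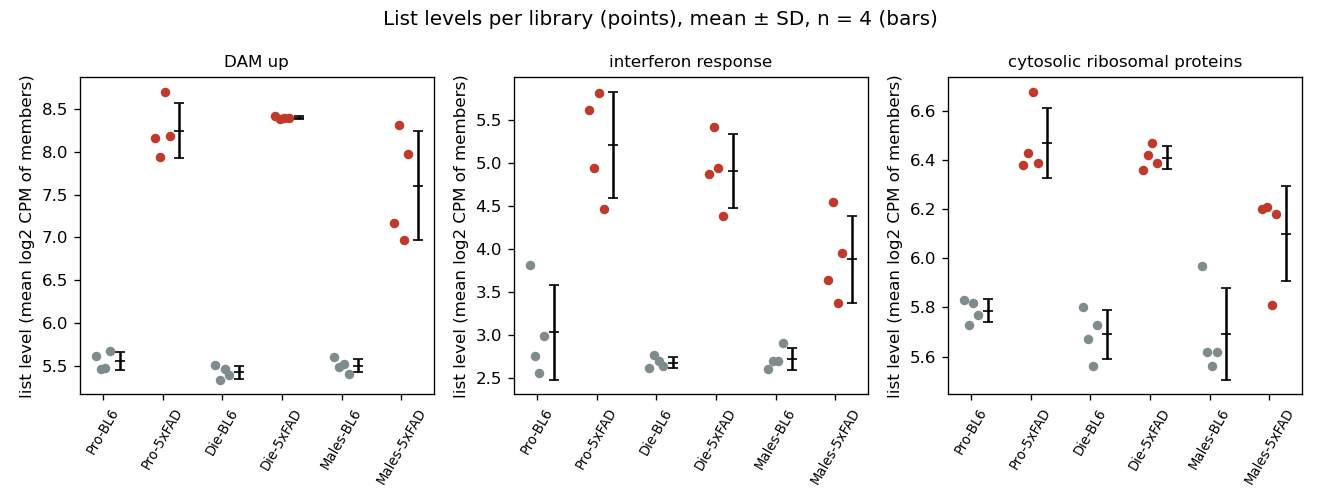
List level (mean log2 CPM of the tested members, vertical axes) of the DAM, interferon-response and cytosolic ribosomal protein lists in each of the 24 libraries by group, BL6 in grey and 5xFAD in red, with the mean and SD of the 4 libraries beside the points. The DAM level averages 8.25 in proestrus 5xFAD, 8.39 in diestrus 5xFAD and 7.6 in male 5xFAD, and between 5.43 and 5.56 in the BL6 groups.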

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

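The counts of regrouped libraries for the 13 planned comparisons, all counts of regrouped libraries outside X and Y, the library-number tests and the scaling test of the ribosomal list were chosen only after the results were seen, as were the permutation tests of list levels and the contrasts averaged over genotypes.

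Among 330 sets of 4 libraries, 18 held a library far from the other 3, where about 1 in 20 sets, or 16, would by chance. Proestrus 5xFAD replicate 3 lay above its group in ribosomal proteins (6.68 against 6.38 to 6.43), lipid genes (5.29 against 4.83 to 4.89), Trem2 (11.9 against 11.5 to 11.6) and Spp1 (6.14 against 4.86 to 5.07), and below it in oligodendrocyte precursor markers (-3.48 against -2.27 to -2.02), all on the log2 CPM scale. Male 5xFAD replicate 3 lay below in ribosomal proteins (5.81 against 6.18 to 6.21) and oxidative phosphorylation (5.97 against 6.18 to 6.22). In male BL6, replicate 1 lay above in ribosomal proteins (5.97 against 5.56 to 5.62), replicate 2 above in oligodendrocyte precursor markers (-2.14 against -3.37 to -3.19) and in Gpnmb (-1.96 against -4.8), and replicate 4 above in glucocorticoid targets (4.87 against 3.5 to 3.6). In diestrus BL6, replicate 3 lay below in lipid genes (3.21 against 3.49 to 3.5) and steroid receptors (4.02 against 4.37 to 4.43), and replicate 4 below in complement genes (5.01 against 5.28 to 5.33). In diestrus 5xFAD, replicate 1 lay above in DAM genes (8.42 against 8.38 to 8.39) and replicate 2 below in steroid receptors (3.94 against 4.68 to 4.71). In proestrus BL6, replicate 1 lay above in mitochondrially encoded genes (5.42 against 5.33 to 5.34) and replicate 3 below in Spp1 (-1.42 against 2.32 to 2.41).

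Lists whose genotype effect differed between groups by camera with its preset correlation numbered 26, and none was called with an estimated correlation. Between proestrus and diestrus these were DAM genes (median -0.17) and mitochondrially encoded genes (-0.23), each with an adjusted p = 0.98 with an estimated correlation. Between proestrus and males they were homeostatic genes (-0.2), DAM genes (0.31), interferon response (0.77), class I genes (0.34), cell cycle (0.44), glycolysis (0.15), oxidative phosphorylation (0.08), ribosomal proteins (0.3), lipid genes (0.3) and TGF-beta signalling (-0.22), with an adjusted p of 0.519 or more with an estimated correlation. Between diestrus and males they were homeostatic genes (-0.23), DAM genes (0.47), interferon response (0.98), class I genes (0.33), cell cycle (0.63), immediate early genes (-0.25), glycolysis (0.24), oxidative phosphorylation (0.1), mitochondrially encoded genes (0.21), ribosomal proteins (0.31), cholesterol synthesis (0.19), lipid genes (0.31), lysosomal genes (0.15) and TGF-beta signalling (-0.27), with an adjusted p of 0.301 or more with an estimated correlation.

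The interferon-response level was higher in the 8 female than in the 4 male 5xFAD libraries by 1.18 (two-sided exact permutation p = 0.00606, adjusted p = 0.0333 over the lists), and by 0.13 in BL6 (exact permutation p = 0.693). A single deviating library was argued against, since with each library left out the highest exact permutation p was 0.0242, without male 5xFAD replicate 1. An effect of the library number common to both genotypes stays open. The differences differed by 1.05 (exact permutation p = 0.0337), but that p is not adjusted over the lists and the test was chosen after the results were seen. Camera with an estimated correlation did not call the list's difference in genotype effect (adjusted p = 0.519 for proestrus and 0.301 for diestrus against males). The female groups also differ in library numbers, with 75 and 76 in BL6 only and 83 in 5xFAD only. A lower general response to the genotype in these males stays open: the DAM level was 0.72 higher in females (exact permutation p = 0.0141, adjusted p = 0.0583 over the lists), and after adjustment for it the interferon difference was 0.64 (permutation p = 0.1). Sex, which the design names, may account for the difference and stays open with these.

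Cytosolic ribosomal proteins had a median of 0.63 in the averaged genotype contrast. Transcript length or GC content was argued against as the whole cause, since 10 genes matched to each member had a median of 0.13 and 95% of 10000 random lists lay below 0.17. Scaling of the libraries was argued against too: a factor per library moves all genes alike, and the list lay 0.49 above its matched genes. Genotype, which the design names, may account for the shift, and this remains a hypothesis.

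Gpx1, Selenow and Selenoh, the last named after its values were seen, had a median difference of 0.67 between females and males averaged over genotypes. In length and GC content 50 genes were matched to each, and these had a median of 0. Such genes thus showed no common shift. Because Gpx1, Selenow and Selenoh were taken from the called genes, that median cannot exclude length or GC content for them. This stays open. Whether selenoprotein genes changed as a class stays open. The other 16 tested had a median of 0.05, with 8 of them higher (camera p = 0.466 with an estimated correlation), but that list leaves out the called genes and its members went both ways, so the bound set beforehand excludes nothing. The number in the library name and sex cannot be told apart, because 0 library numbers held both sexes. Sex may account for the difference but is open for that reason.

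Regrouping the libraries bears on the counts. The real split alone gave as many genes, 1 of 35 splits, for genotype in proestrus (1334, highest other 0), in diestrus (1813, 419) and in males (469, 192). These regroupings were chosen after the results were seen, and 1 of 35 is their smallest share, so by themselves they do not exclude chance. The 3 comparisons share no library, yet 387 genes were called higher in all 3, against 1.65 for independent lists. That overlap argues against chance. The real split also stood alone, 1 of 35, for proestrus against males in BL6 (14, 2) and 5xFAD (68, 20) and diestrus against males in BL6 (10, 1) and 5xFAD (17, 1), but there sex chromosome genes favour the real split. With X and Y genes left out before the adjustment, 1 of 35 splits was as large for proestrus against males in BL6 (5, highest other 2) and 5xFAD (35, 19). The comparisons were planned, but these regroupings were chosen after the results were seen, and 1 of 35 is the smallest share they can give. Whether chance can be excluded there stays open. For diestrus against males 2 of 35 splits were as large in BL6 (1, 1) and 3 of 35 in 5xFAD (1, 1), so there chance cannot be excluded. Of 100 splits the real one alone was as large for averaged genotype (3837, 416). That regrouping was chosen after the results were seen as well, so it argues against chance without excluding it. The real one of 100 also stood alone for proestrus against diestrus averaged over genotypes (5, 1) and females against males averaged over genotypes (103, 1, and outside X and Y 73, 1), but these contrasts, unlike the others, were not planned and were chosen after the single comparisons of the same libraries were seen, so whether chance can be excluded stays open. The 5 fell to 0 with the library number as a factor and without proestrus BL6 replicate 1, proestrus 5xFAD replicate 1 or 4, diestrus BL6 replicate 2 or 3, or diestrus 5xFAD replicate 3. With 0 genes called by edgeR, all 35 splits were as large for proestrus against diestrus in BL6 and in 5xFAD (highest other 1 in each), and all 100 for the 3 differences between genotype effects (highest other 1, 3 and 1), by construction, and chance cannot be excluded. At an unadjusted p under 0.05 these 5 comparisons had 1286, 1164, 640, 873 and 1083 genes, and DESeq2 called 14, 10, 2, 5 and 1.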

How the results depend on the processing

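The fit without the 3 libraries that stand apart and the adjustment without X and Y genes were chosen only after the data were seen, and the other alternatives were planned. Counts of genes for genotype in proestrus, in diestrus and averaged stayed within 1.5 times of the value given under every alternative not named here. DESeq2 called 780 genes for genotype in males, 14 and 10 for proestrus against diestrus in BL6 and 5xFAD, 81 and 267 for proestrus against males in BL6 and 5xFAD, 231 for diestrus against males in 5xFAD, and 2, 5 and 1 for the differences in genotype effect between proestrus and diestrus, proestrus and males, and diestrus and males. Voom with quality weights called 1 for proestrus against diestrus in BL6, 27 and 104 for proestrus against males in BL6 and 5xFAD, and 141 for diestrus against males in 5xFAD. The fit to the compared groups only called 1166 for genotype in diestrus and 10 for proestrus against males in 5xFAD. For the last comparison the count was 35 with no filter, 33 with the replicate block and 24 without the 3 libraries that stand apart. Without X and Y genes 7 were left for proestrus against males in BL6, 1 for diestrus against males in BL6 and 7 for diestrus against males in 5xFAD, because fewer genes were counted. With X and Y genes left out before the adjustment, edgeR called 5 and 35 for proestrus against males in BL6 and 5xFAD and 1 and 1 for diestrus against males, because fewer small p entered the adjustment, and of the genes examined singly 16 kept their side of the threshold and 9 did not. For the other alternatives the cause was not tested. Leaving out each library gave 793 (without proestrus 5xFAD replicate 3) to 1299 for genotype in proestrus, 1314 to 2184 in diestrus, 224 (without male 5xFAD replicate 2) to 644 (without male 5xFAD replicate 3) in males and 3382 to 4763 averaged. It gave 0 to 2 for proestrus against diestrus in BL6 (2 without proestrus BL6 replicate 3), 12 to 21 and 12 to 125 for proestrus against males in BL6 and 5xFAD, 8 to 10 and 9 to 53 for diestrus against males in BL6 and 5xFAD, and 0 to 1 for the difference between proestrus and males (1 without proestrus 5xFAD replicate 1). The replicate numbers share only a number: 0 of 60 same-numbered pairs had a correlation over 0.1 (-0.12 to 0.07), 9 of 24 libraries correlated best with their own number, and with the replicate block 146 genes examined singly kept their side of the threshold and 15 did not. In males the library-name numbers 77, 79, 81 and 84 each held a BL6 and a 5xFAD library. Correlations within these pairs were 0.06, 0, 0.06 and 0.07, and the main model did not use the pairing. Signs turned for P2ry12 in male genotype without the 3 libraries (-0.01), oxidative phosphorylation in diestrus against male BL6 without diestrus BL6 replicate 3 (0.01, with a lowest value of -0.11 without diestrus BL6 replicate 1), ribosomal proteins in proestrus against diestrus 5xFAD without proestrus 5xFAD replicate 3 (0) and lysosomal genes there with the library number as a factor (0.04). The library-number factor could not be fitted for the sex comparisons. With an estimated correlation 58 list results kept their side of the threshold and 92 did not. Depth limits genes near the floor of 3 counts per library.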

Other observations

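The contrasts averaged over genotypes were chosen only after the single comparisons were seen, and every gene of this part was named after its values were seen.

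Across both genotypes, a set of single genes differed between female and male microglia. No library number held both sexes, so for none of these genes can sex be told apart from that number. The selenoenzyme Gpx1 (0.67 ± 0.06, edgeR adjusted p = 1.89e-08) and the selenoproteins Selenow (0.73 ± 0.08, edgeR adjusted p = 8.02e-06) and Selenoh (0.43 ± 0.08, edgeR adjusted p = 0.00926) were higher in females. The calcium-permeable channels Trpv4 (1.09 ± 0.15) and Trpm2 (0.33 ± 0.06), the glucose transporter Slc2a3 (0.81 ± 0.13), the inflammasome sensor Nlrp3 (0.47 ± 0.07) and the survival factor Bcl2 (0.73 ± 0.14) were also higher, at edgeR adjusted p of 0.000324, 0.0102, 0.00259, 0.000965 and 0.0176. The transcription factor Klf2 was lower (-1.22 ± 0.19, edgeR adjusted p = 0.00198), at 8.81 ± 5.26 CPM in male BL6 and 8.64 ± 1.98 in male 5xFAD against 3.2 ± 0.385 to 4.41 ± 1.13 in the female groups (SD, n = 4). The highest male BL6 library had 16.5 CPM. Klf2 is a member of the immediate early and dissociation list, whose level averaged 4.29 in male BL6 and 4.81 in male 5xFAD, against 3.98 to 4.47 in the female groups. Whether cell dissociation accounts for the Klf2 difference was not tested. Fchsd2 (-0.37 ± 0.06) and Banp (-0.43 ± 0.08) were lower as well. Within 1 genotype, diestrus against males called Gpx1 alone of these genes by edgeR. The Nlrp3 difference came mainly from proestrus, at 79.4 ± 8.21 CPM in BL6 and 74.1 ± 8.8 in 5xFAD, against 55.9 ± 4.4 and 51.5 ± 6.92 in diestrus and 45.2 ± 4.64 and 47.4 ± 7.17 in males (SD, n = 4). Of the genes named in this paragraph, all but Bcl2, which was called in 23, stayed called with each of the 24 libraries left out in turn. edgeR called 103 genes, 66 higher and 37 lower in females, 90 of them outside X and Y (73 with X and Y genes left out before the adjustment), and DESeq2 called 423. The edgeR count was 54 and 68 without proestrus BL6 replicates 1 and 2, 55 without diestrus 5xFAD replicate 1, 67 without diestrus BL6 replicate 2, 58, 38 and 40 without male BL6 replicates 1, 3 and 4, and 46, 49 and 64 without male 5xFAD replicates 1, 3 and 4.

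Across both genotypes, proestrus microglia were higher than diestrus ones in Nlrp3 (0.52 ± 0.08, edgeR adjusted p = 0.0213) and N4bp3 (1.6 ± 0.27, edgeR adjusted p = 0.0285), and lower in Scaf8 (-0.38 ± 0.07), Zmym4 (-0.39 ± 0.07) and Smurf2 (-0.37 ± 0.07), each at an edgeR adjusted p of 0.0446. The calls depended on single libraries, while the log2 differences kept their size: over the leave-outs Nlrp3 ran from 0.48 to 0.55, N4bp3 from 1.44 to 1.77, Scaf8 from -0.43 to -0.36, Zmym4 from -0.42 to -0.36 and Smurf2 from -0.41 to -0.34. Over the 24 leave-outs Nlrp3 was called in 18, N4bp3 in 15, Scaf8 in 4, Zmym4 in 3 and Smurf2 in 2. edgeR called 0 without proestrus BL6 replicate 1, proestrus 5xFAD replicates 1 or 4, diestrus BL6 replicates 2 or 3, or diestrus 5xFAD replicate 3. It called 1 without proestrus 5xFAD replicate 2 or diestrus 5xFAD replicate 2, 3 without proestrus BL6 replicate 4 and 8 without diestrus BL6 replicate 4. It called 2 without proestrus BL6 replicate 2, proestrus 5xFAD replicate 3, diestrus BL6 replicate 1, diestrus 5xFAD replicates 1 or 4, male BL6 replicates 1, 2, 3 or 4, or male 5xFAD replicates 1, 3 or 4. With the library number as a factor edgeR called 0, and DESeq2 without it called 72.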
